A study of Mus musculus with 6 samples.

How the data were processed

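RNA from renal cortex was measured on 6 1-colour Agilent arrays, 3 from diabetic WT mice and 3 from diabetic C3aR-/- mice, and groups were taken from the sample titles. Per the labels' protocols, mice of 8 weeks were fed a diet with 60% of calories from fat for 4 weeks and then given streptozotocin at 60 mg/kg on 3 days, and 0.2 µg of RNA was labelled with Cy3. Per the file headers, Agilent Feature Extraction 10.7.1.1 read 62976 spots per array on a grid built on mm9, and all 6 arrays lay on 1 slide and in 1 scan, so slide and scan could not be fitted as blocks. The deposited intensity values used were the processed signal, which per the file headers is background-subtracted and spatially detrended but not normalized between arrays, and the mean spot and local background signals. Scanner flags for outlier, saturated and well-above-background spots came from the same files. The authors' deposited table holds log2 values. Its columns hold the same sorted values (largest difference 0.000865), as quantile normalization gives, each has a median of 5.73, and each tracks the processed signal of its own array with r of at least 0.999; the tool, background step and filters behind it are not given in the sources used here.

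Control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and 6 probes were left out because of flags. No probe was saturated. Values were log2 of the processed signal minus each array's 75th percentile. Of 56605 probes, 34778 were well above background on at least 3 arrays and were kept, and for each gene the probe with the highest mean over all 6 arrays was used, giving 22741 genes. A symbol was taken through the accession in the RefSeq table of GRCm38.p6 for 32994 probes, and the name in the files was kept for 23611. Among tested genes 7862 had over 1 probe; of the named genes, Atf4, Lpl, Myh11, Nsdhl, Per3 and Rgma had probes of opposite direction.

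Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment. Of 37 gene lists fixed before the data were examined, 36 had at least 5 tested members and entered camera with a preset correlation of 0.01; the list of sex chromosome genes had 4 and was not tested. An estimated correlation and fry were alternatives. List means per array were compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3. Genes not well above background on any array of a group have a bound in place of a fold. The tests were run first on simulated data with known changes: no gene was called in simulated data without changes, and 0 of 36 lists. Simulated genes varied independently of each other, so this does not check camera where genes move together. Among the other splits of the real arrays into 3 and 3, camera called from 7 to 24 lists.

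The genes named were fixed by a rule before the data were examined: C3ar1; the 10 largest rises and 10 largest falls past the adjusted threshold with groups that do not overlap and with a gene symbol, filled from genes with an unadjusted p under 0.01 where fewer passed; and 2 members with the smallest p in each list, or 4 in a list past camera. Since no gene passed, all 20 came from the filling step. Values of a few single genes, in lists or taken by this rule, are not reported here. Alternatives were quantile normalization, median scaling, normexp with an offset of 50, the authors' table, no filter, a filter on all 6 arrays, the mean of probes, single probes, trend and robust variances, array weights, the replicate number as a block and leaving out each array. Leaving out both arrays at the ends of the first principal component (43.1% of the variance), which are WT replicate 1 and C3aR-/- replicate 2, and the row of the slide as a block were added after the data were seen. Those end arrays lie in opposite groups, so leaving both out was bound to weaken differences that follow this component. Array correlations ranged from 0.981 to 0.995. Figures were drawn with matplotlib 3.10.9.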

Results

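RNA was measured in the renal cortex of male C57BL/6 mice made diabetic by a high-fat diet and streptozotocin, a toxin of the insulin-producing beta cells. One group of 3 samples came from wild-type (WT) mice and the other group of 3 from mice lacking the C3a receptor (C3aR-/-), through which the complement fragment C3a acts on cells. The mice were killed 26 weeks after streptozotocin. The non-diabetic groups of the study were not analysed here, so the comparison shows how the 2 genotypes differed within diabetes and not what diabetes changed. On each 1-colour array, between 58.6% and 63.0% of the 56605 probes were well above background. Levels are log2 signals relative to the array's 75th percentile, differences are C3aR-/- minus WT, and errors of differences are limma standard errors over 3 arrays per group. The number of arrays limits the precision. Nothing in the labels says that the replicates were separate animals, so limma and permutation p-values measure the spread between these samples. Camera with its preset correlation and Fisher's exact test set genes against other genes, so their p-values do not measure that spread.

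C3ar1, the targeted gene, read lower in the C3aR-/- arrays. Its level was -3.48 ± 0.47 (SD, n = 3) in WT and -4.58 ± 0.44 (SD, n = 3) in C3aR-/-, a difference of -1.10 ± 0.30, or 0.466 of the WT level. The WT arrays read -2.96, -3.86 and -3.62 and the C3aR-/- arrays -4.10, -4.95 and -4.69, with no overlap between the groups. The probe was well above background on 3 WT arrays and 2 C3aR-/- arrays. It lies at chromosome 6, 122798222 to 122798281 (mm9), and whether that stretch is inside the deleted part is not given in the sources used here, so its residual signal checks the labels only in part. Over all genes the difference did not pass adjustment (limma, adjusted p = 0.931). Its size dropped to -0.39 with normexp background correction and to -0.65 without WT replicate 1 and C3aR-/- replicate 2, the arrays at the ends of the first principal component. Macrophage genes were also lower in C3aR-/- (median -0.54), and the arrays cannot separate loss of C3ar1 from fewer cells that express it.

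The question of the comparison, from the title of the series, is what loss of the receptor does to the diabetic kidney. Among the 20 genes named for their size of change, the lower readings in C3aR-/- cortex were the larger ones. Ccl1, a chemokine of activated T cells, read -1.97 in WT and -3.86 in C3aR-/-, a difference of -1.90 ± 0.31. Slamf6, a receptor of T and natural killer cells (probe at chromosome 1, 173866817 to 173868145, mm9), differed by -1.69 ± 0.17 and had the smallest p of all genes, and Sh2d1a, which encodes the adaptor that binds receptors of the Slamf6 family, differed by -1.75 ± 0.29. Cd2, an adhesion receptor of T cells, differed by -1.46 ± 0.32, and Cd3g, a chain of the T cell receptor complex, by -1.44 ± 0.37.

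The other negative differences among them were Serpinb9e, of a family of granzyme inhibitors, at -2.74 ± 0.54, Apol7c at -1.95 ± 0.41, Izumo1r at -1.70 ± 0.39, Cd163l1 at -1.47 ± 0.33 and Il1f6, an interleukin-1 family cytokine, at -1.47 ± 0.32. Serpinb9e, Sh2d1a and Slamf6 were not well above background on any C3aR-/- array, so their folds are bounds. In the processed signals, WT exceeded C3aR-/- at least 1.84-fold for Serpinb9e, at least 2.33-fold for Sh2d1a and at least 1.63-fold for Slamf6, taking the dim group at the lowest signal well above background on each array or at its own reading where higher. With normexp correction, whose offset shrinks folds of dim probes by construction, these 3 differed by -0.51, -0.44 and -0.33, under those bounds, and Apol7c by -1.15, Ccl1 by -1.01, Izumo1r by -0.82 and Cd163l1 by -0.51. The positive differences were smaller. They were found in Nap1l5 (0.71 ± 0.19), Olfr681 (0.69 ± 0.19), Nkx6-1 (0.68 ± 0.14), Brd8dc (0.64 ± 0.17), Hsd17b1 (0.63 ± 0.17), Myh6, the alpha cardiac myosin heavy chain (0.61 ± 0.16), Rgma (0.58 ± 0.15), Amy2a5 (0.57 ± 0.11) and Slc38a4, an amino acid transporter (0.53 ± 0.13). Rnf224 read 0.80 ± 0.14 but was not well above background on any WT array, so its fold is a bound too, at least 1.39-fold higher in C3aR-/-. With normexp correction it differed by 0.27, Nap1l5 by 0.31, Olfr681 by 0.38, Nkx6-1 by 0.29, Brd8dc by 0.39, Hsd17b1 by 0.22 and Amy2a5 by 0.27. Another probe of Rgma read in the opposite direction, and the mean of its probes was 0.24. Another probe of Izumo1r differed by -0.59 ± 0.45.

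**Figure D1:**
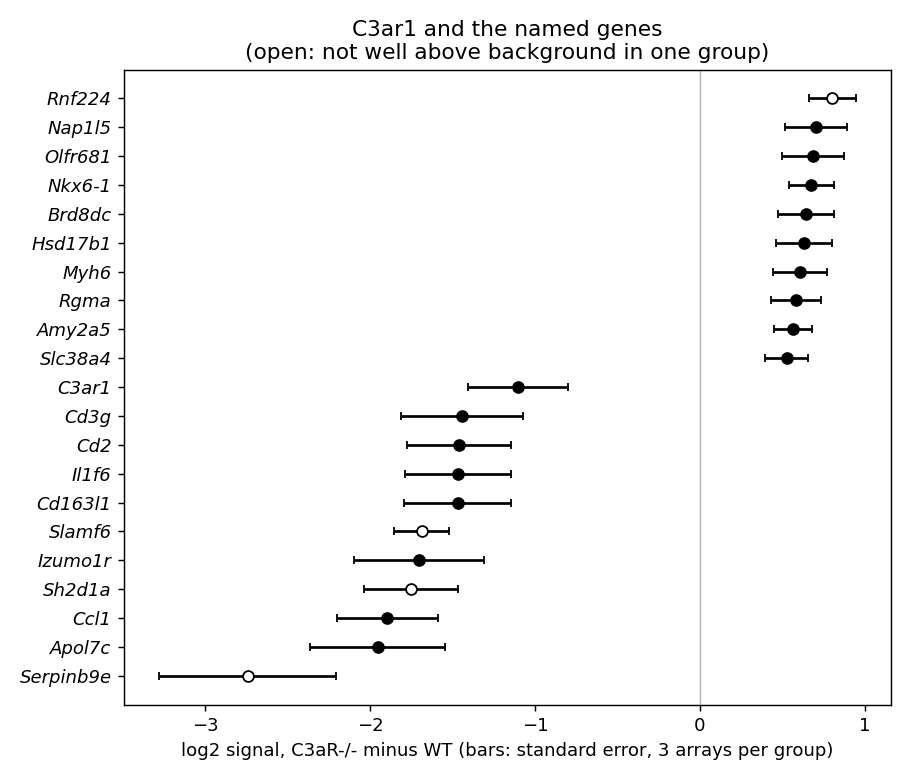
Log2 difference in signal, C3aR-/- minus WT (horizontal axis), for C3ar1 and the 20 named genes, with bars for the standard error over 3 arrays per group and open circles for genes not well above background on any array of one group. Among filled circles the negative differences reach -1.95 for Apol7c and the positive ones 0.71 for Nap1l5, while open circles show readings whose folds are known only as bounds.

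None of these genes passed the threshold over the 22741 genes tested. At an adjusted p under 0.05 limma called 0 genes, and the lowest adjusted p was 0.858, for Slamf6. At an unadjusted p under 0.05 there were 1111 genes (4.89%), of which 609 were lower and 502 higher in C3aR-/-. With the further requirement of at least 2-fold there were 136, and 114 of these were lower. The 2 groups did not overlap for 2238 genes, or 9.84%, where chance gives 10%. In simulated data with the same spread, 34% of 50 genes changed 2-fold and 80% of 50 genes changed 4-fold were called among 22741 genes. Simulated genes varied independently, and these shares depend on how many genes change, so they may not carry over to the real arrays. Simulated data without changes gave 82 genes with an unadjusted p under 0.05 and at least 2-fold, against the 136 here. The share of genes with an unadjusted p under 0.05 was 5.35% in those data, above the 4.89% here. The count of 136 moved to 20 with normexp background correction, 77 among probes well above background on all arrays, 320 without a filter, 239 without WT replicate 2 and 250 without C3aR-/- replicate 3.

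Genes of T cells were lower as a group in C3aR-/- cortex. Of 34 measured members of the T cell list, 31 were lower, with a median difference of -0.94, and 21 passed adjusted over the list alone (0 did over all genes tested). Cd6, a co-receptor of T cells, differed by -1.22 ± 0.21, Il2rb, a chain of the interleukin-2 receptor, by -0.92 ± 0.19, Cd2 by -1.46 ± 0.32 and Sh2d1a, not well above background on any C3aR-/- array, by -1.75 ± 0.29 (at least 2.33-fold in the processed signals, and -0.44 with normexp correction). Among the 3 members that were not lower were Cd4 (0.060) and Gata3 (0.021), named here after their values were seen. The mean of the list was 0.49, 0.17 and 0.59 on the WT arrays and -0.36, -0.76 and -0.12 on the C3aR-/- arrays (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Camera with its preset correlation gave an adjusted p of 1.80e-26 and the call was lost with an estimated correlation (adjusted p = 0.304). Without WT replicate 3 the count of 21 went to 0, without WT replicate 1 to 14 and without both arrays at the ends of the first component to 0, while the median was -0.84, -0.90 and -0.65, and with normexp correction it was -0.52.

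**Figure D2:**
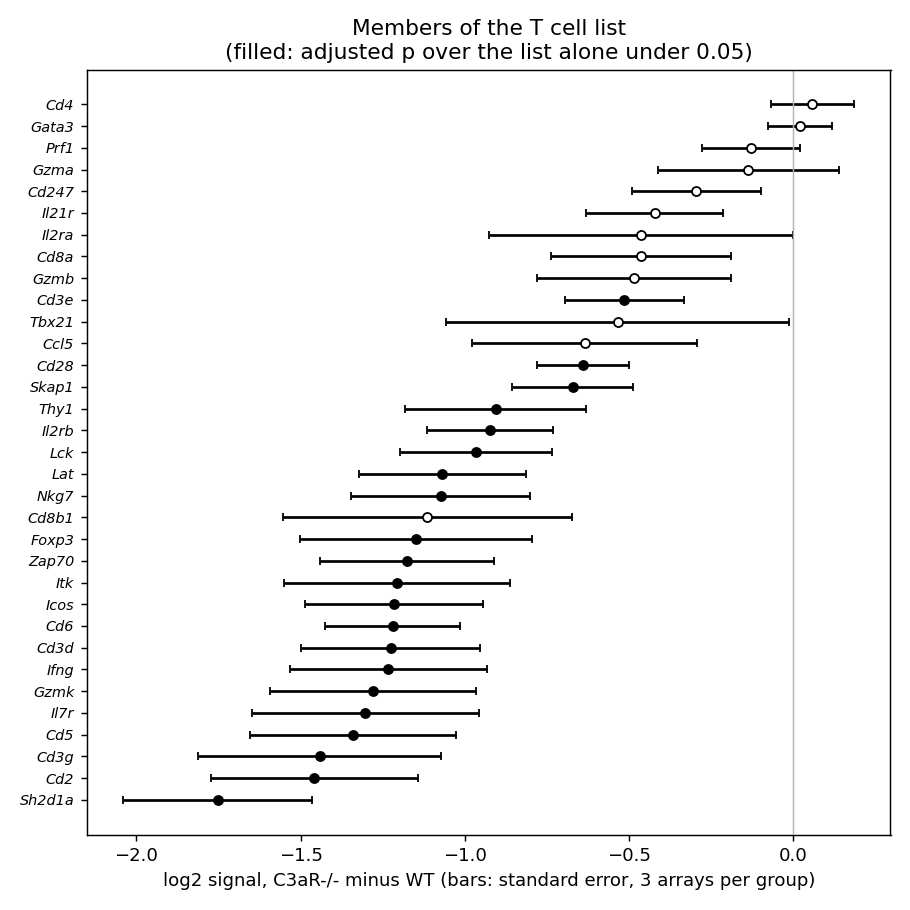
Log2 difference in signal, C3aR-/- minus WT (horizontal axis), for 33 of the 34 measured members of the T cell list, with bars for the standard error over 3 arrays per group and filled circles for the 21 members past an adjusted p of 0.05 over the list alone. Cd2 reads -1.46 and Cd4 0.060, and the lowest reading is that of Sh2d1a, not well above background on any C3aR-/- array, so its fold is a bound.

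Chemokines and their receptors were also lower, 35 of 41 measured members with a median of -0.58. Ccr6, a receptor of T and B cells, differed by -1.10 ± 0.18 and was the single member past adjustment over the list alone (0 over all genes). Xcl1 (-1.38 ± 0.30), a chemokine of T and natural killer cells, Cxcr3 (-1.25 ± 0.31), the receptor for interferon-induced chemokines, and Ccl4 (-0.55 ± 0.14) did not pass it. With normexp correction Ccr6 differed by -0.31 and Xcl1 by -0.84. The count of 1 ranged from 0 to 11 over the arrays left out in turn. The list means of the groups did not overlap (exact permutation p = 0.1). Against the other genes, camera gave an adjusted p of 2.96e-14, and the adjusted p with an estimated correlation was 0.304. The median was -0.38 without WT replicate 1, -0.31 with normexp correction, -0.35 with array weights and -0.16 without both end arrays.

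Macrophage genes were lower in 29 of 30 measured members, with a median of -0.54. Lyz2 (-0.92 ± 0.21), the lysozyme of myeloid cells, Lyz1 (-0.89 ± 0.18), another lysozyme gene, Gpnmb (-1.27 ± 0.39) and C1qa (-0.69 ± 0.21), a chain of complement C1q, had the smallest p. No member passed adjusted over the list alone or over all genes, and 13 had an unadjusted p under 0.05. The count of 13 was 3 without WT replicate 1, 4 without WT replicate 3, 4 without C3aR-/- replicate 2 and 20 without WT replicate 2, where 14 passed over the list alone. Gpnmb differed by -0.77 with normexp correction. Camera gave the list an adjusted p of 1.17e-16, and the adjusted p with an estimated correlation was 0.402. The median was -0.25 with array weights and -0.26 without both end arrays.

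Genes of antigen presentation followed the same direction. All 15 MHC class II genes measured were lower, with a median of -0.49, among them H2-Oa (-0.63 ± 0.18), H2-Eb1 (-0.52 ± 0.18), the protease Ctss (-0.62 ± 0.23) and the co-stimulator Cd86 (-0.53 ± 0.23). For class II, camera gave an adjusted p of 1.72e-08, and the adjusted p was 0.314 with an estimated correlation. Of 18 MHC class I genes, 17 were lower with a median of -0.32, including the peptide transporter Tap2 (-0.82 ± 0.23), H2-M3 (-0.53 ± 0.23), H2-T10 (-0.34 ± 0.16) and H2-T22 (-0.31 ± 0.14), at a camera adjusted p of 9.37e-08 and an adjusted p of 0.405 with an estimated correlation. No member of either list passed adjusted over the list alone or over all genes. Over the list alone, 7 class II members passed without C3aR-/- replicate 3 and 3 with the replicate block, and 11 class I members passed with the slide row as a block. H2-Oa differed by -0.30 with normexp correction, Cd86 by -0.31 without C3aR-/- replicate 2 and H2-M3 by -0.35 without WT replicate 1. The class II median was -0.31 without C3aR-/- replicate 2, -0.31 with array weights, -0.30 with normexp correction and -0.28 without both end arrays, and the class I median was -0.18 without WT replicate 1, -0.51 without C3aR-/- replicate 3 and -0.061 without both end arrays, where its call ended (adjusted p = 0.196).

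Interferon-induced genes were lower in 41 of 42 measured members, with a median of -0.56. Cxcl9 (-1.39 ± 0.36), a chemokine induced by interferon-gamma, Ddx60 (-0.74 ± 0.22), Oasl1 (-0.58 ± 0.22) and Trim30a (-0.55 ± 0.21) had the smallest p, and no member passed adjusted over the list alone or over all genes. The group means overlapped, since WT replicate 1 stood at 0.73 and the other WT arrays at 0.098 and -0.014 while C3aR-/- replicate 3 stood at 0.15 (exact permutation p = 0.3). WT replicate 1 and C3aR-/- replicate 3 are the 2 arrays of slide row 2, and within each row WT stood higher, since the other C3aR-/- arrays were at -0.34 and -0.62. The median was -0.54 within row 1 and -0.57 in row 2, and with the row as a block, chosen after the data were seen, 27 members passed over the list alone. Ddx60 differed by -0.33 with normexp correction. Set against the other genes by camera, the list had an adjusted p of 1.41e-17, and the adjusted p with an estimated correlation was 0.402. Without WT replicate 1 the median was -0.30, without C3aR-/- replicate 2 it was -0.35, with array weights -0.37 and without both -0.11.

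Smaller negative differences were found in other inflammatory lists. Inflammatory cytokines were lower in 17 of 20 members (median -0.29), with Il18r1 (-1.08 ± 0.24), the interferon-gamma gene Ifng (-1.23 ± 0.30), Casp1 (-0.57 ± 0.18) and Nos2 (-0.29 ± 0.10). Genes of Toll-like receptors and NF-kB signalling were lower in 25 of 31 members (median -0.21), with Tlr6 (-0.72 ± 0.15), Tlr2 (-0.59 ± 0.23), Nfkb2 (-0.47 ± 0.18) and Tlr3 (-0.30 ± 0.11). B and plasma cell genes were lower in 11 of 14 (median -0.28), and Cd79b, a chain of the B cell receptor, at -0.66 ± 0.15, was the single member past adjustment over the list alone (0 over all genes, and 0 to 2 over the arrays left out in turn). Pou2af1 differed by -0.95 ± 0.27 and Sdc1 by -0.32 ± 0.16. Complement genes were lower in 21 of 34 (median -0.10), with the complement receptor chain Itgax (-0.80 ± 0.18), C1qa (-0.69 ± 0.21), C1qb (-0.60 ± 0.21) and the C5a receptor C5ar1 (-0.86 ± 0.30). The complement list shares 4 genes with the macrophage list, whose median was -0.54, and the 29 complement genes outside the leukocyte lists had a median of -0.066. In camera the adjusted p of these 4 lists were 2.87e-06, 3.09e-07, 0.00128 and 0.00731, and with an estimated correlation the adjusted p were 0.402, 0.402, 0.304 and 0.402. The B cell call ended without C3aR-/- replicate 2 (adjusted p = 0.0509) and without both end arrays, the complement call without WT replicate 3, without C3aR-/- replicate 2, with array weights and without both, and the other 2 calls without both. The cytokine median was -0.16 without WT replicate 1, -0.17 without C3aR-/- replicate 2, -0.18 with normexp correction, -0.099 with array weights and 0.022 without both. The Toll-like receptor median was -0.14 without WT replicate 1, -0.36 without WT replicate 2, -0.11 with array weights and -0.060 without both. The B cell median was -0.14 without C3aR-/- replicate 2, -0.12 with normexp correction, -0.16 with array weights, -0.17 without a filter and with the filter on all arrays, and -0.13 without both, and the complement median was -0.15 without WT replicate 2 and -0.051 without C3aR-/- replicate 2. With normexp correction Il18r1 differed by -0.48, Ifng by -0.61, Nos2 by -0.14, Tlr6 by -0.19, Tlr3 by -0.17, Pou2af1 by -0.25 and C5ar1 by -0.43. Without C3aR-/- replicate 2, Tlr2 differed by -0.37 and Nfkb2 by -0.30, without WT replicate 1 Sdc1 by -0.17 and without WT replicate 3 C5ar1 by -0.57. No cytokine, Toll-like receptor or complement member passed over the list alone, against 3, 1 and 5 without WT replicate 2 and 2, 0 and 1 without C3aR-/- replicate 3.

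Markers of injured tubules were lower in 30 of 32 measured members, with a median of -0.47. Sox9, a transcription factor of regenerating tubule cells, differed by -0.60 ± 0.10 and was the single member past adjustment over the list alone (0 over all genes), and 0 did without any 1 of the arrays. Another probe of Sox9 differed by -0.29 ± 0.21. Lcn2 (-1.21 ± 0.44), which encodes the injury marker NGAL and is also a neutrophil gene, Krt19 (-0.80 ± 0.27) and ceruloplasmin Cp (-0.74 ± 0.26) had larger errors. WT replicate 1 stood at 0.71 on this list and the other WT arrays at -0.036 and 0.0097, while C3aR-/- replicate 3 stood at -0.0026 (exact permutation p = 0.2). The median was -0.30 within slide row 1 and -0.72 in row 2, and 6 members passed over the list alone with the row as a block. Without WT replicate 1, Lcn2 differed by -0.68. In camera the adjusted p was 4.43e-11, and the adjusted p with an estimated correlation was 0.402. The median was -0.19 without WT replicate 1, -0.27 without C3aR-/- replicate 2, -0.16 with array weights and -0.035 without both, where the call ended (adjusted p = 0.196). Fibrosis and matrix genes were lower in 37 of 46 (median -0.19), with Mmp7 (-1.41 ± 0.32), S100a4 (-0.82 ± 0.21) and Timp1 (-0.99 ± 0.38) and, in the other direction, Acta2 (0.38 ± 0.18). Mmp7 differed by -0.54 with normexp correction and Timp1 by -0.63 without WT replicate 1. Their camera adjusted p was 9.95e-06 and the adjusted p with an estimated correlation was 0.529. The median was -0.068 without WT replicate 1, -0.31 without WT replicate 2 and -0.32 without C3aR-/- replicate 1, and the call ended without C3aR-/- replicate 2 (-0.050), with array weights (0.048) and without both end arrays (0.032).

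Genes of the proximal tubule read higher in C3aR-/-, 35 of 37 members with a median of 0.31, but no member had an unadjusted p under 0.05. The phosphate transporter Slc34a3 (1.23 ± 0.60), Slc6a19 (0.75 ± 0.44), Slc5a12 (0.70 ± 0.39) and Ass1 (0.50 ± 0.22) had the smallest p. Without WT replicate 1 these 4 differed by 0.54, 0.46, 0.32 and 0.30, without WT replicate 2 Slc6a19 differed by 1.15 and Slc5a12 by 1.05, and without C3aR-/- replicate 2 Slc6a19 by 0.47. Oxidative phosphorylation genes were higher in 48 of 48 members by a median of 0.16, including Uqcrb (0.18 ± 0.11), Cox7a2 (0.22 ± 0.15), Uqcrfs1 (0.23 ± 0.15) and Ndufa9 (0.21 ± 0.15), which were 0.12, 0.11, 0.10 and 0.13 without C3aR-/- replicate 2 and 0.13, 0.13, 0.15 and 0.090 without WT replicate 1. Fatty acid oxidation genes were higher in 39 of 45 (median 0.20), although Angptl4 (-0.42 ± 0.18) and Slc25a20 (-0.76 ± 0.34) were lower beside Fabp3 (0.38 ± 0.17) and Slc27a2 (0.23 ± 0.12). Without WT replicate 1, Angptl4 differed by -0.26 and Slc27a2 by 0.13. For the 3 lists camera gave adjusted p of 0.000281, 6.06e-06 and 0.00681, and with an estimated correlation the adjusted p were 0.608, 0.608 and 0.630. These calls rested on WT replicate 1, at -0.81 on the proximal tubule list, and C3aR-/- replicate 2, at 0.47. Without WT replicate 2 the proximal tubule median was 0.48. Without WT replicate 1 the medians were 0.042, 0.056 and 0.071, without C3aR-/- replicate 2 they were 0.10, 0.061 and 0.033, no longer called in either case, and without both they turned negative (-0.13, -0.039 and -0.094) and were called lower (camera adjusted p of 0.000482, 0.0287 and 0.00333). With array weights they were -0.028, 0.027 and -0.0029, not called. Leaving out both end arrays was bound to weaken lists that follow the first component, so the turn to negative medians is not evidence of lower levels.

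Genes of the distal tubule and collecting duct were higher in 21 of 25 members by a median of 0.13. They included Scnn1a, a subunit of the epithelial sodium channel (0.27 ± 0.092), Slc26a4, the anion exchanger pendrin (0.27 ± 0.098), Trpm6, a magnesium channel (0.30 ± 0.13), and the calcium-binding Calb1 (0.35 ± 0.15). Trpm6 differed by 0.20 without C3aR-/- replicate 2. No member passed adjusted over the list alone or over all genes. The list means did not overlap (exact permutation p = 0.1). The camera adjusted p was 0.00755 and the adjusted p with an estimated correlation was 0.304. Fry, which asks whether the genes of a list move on balance one way, gave an adjusted p of 0.00871, the one list it called. Without WT replicate 2 the camera call ended (adjusted p = 0.0515), and the median was 0.20 without C3aR-/- replicate 2 and with array weights.

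**Figure D3:**
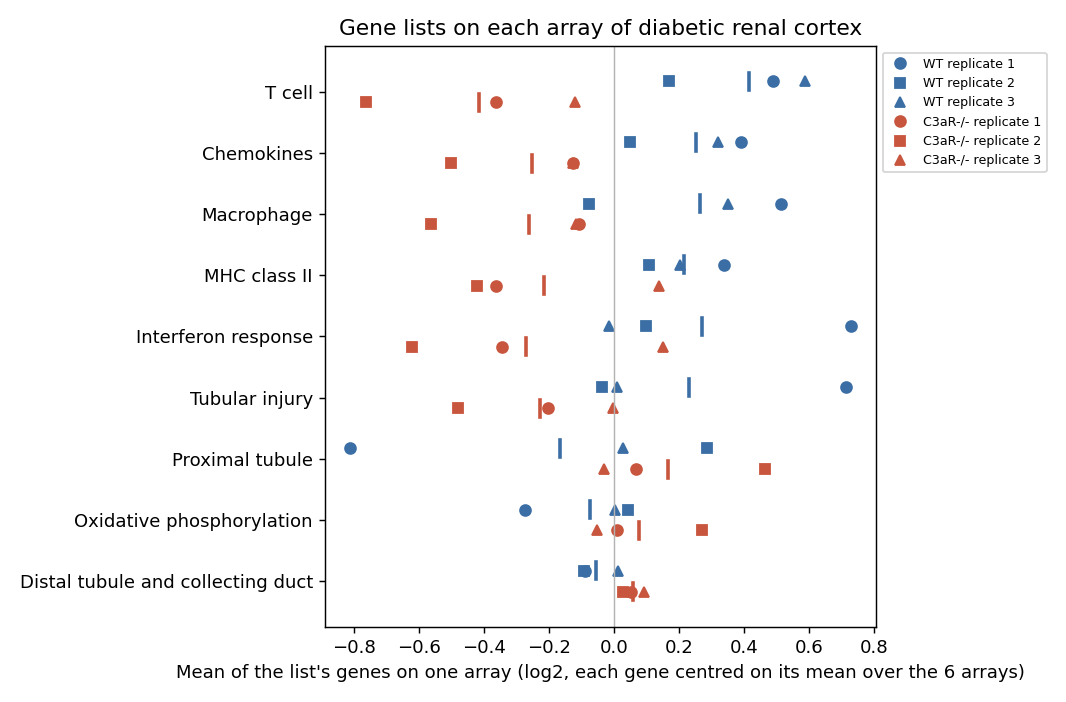
Mean of the measured genes of 9 lists on each array (horizontal axis, log2, each gene centred on its mean over 6 arrays), with 1 symbol per array, WT in blue and C3aR-/- in red, and vertical bars for the group means. WT replicate 1 lies apart from the other WT arrays on the interferon, tubular injury and proximal tubule lists, and the groups do not overlap on the T cell, chemokine, macrophage and distal tubule lists.

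Cholesterol synthesis genes were higher in 22 of 23 (median 0.22), with Dhcr7 (0.36 ± 0.16), Lss (0.34 ± 0.15), Nsdhl (0.32 ± 0.17, with another probe opposite) and Hsd17b7 (0.31 ± 0.17). ER stress genes were lower in 19 of 25 (median -0.13), with Pdia3 (-0.42 ± 0.23), Pdia6 (-0.17 ± 0.11) and Eif2ak3 (-0.14 ± 0.093) lower and Atf4 (0.21 ± 0.12) higher on one probe and lower on another. The camera adjusted p of the 2 lists were 0.000377 and 0.00597, and with an estimated correlation both adjusted p were 0.508. The cholesterol call ended without WT replicate 1, without C3aR-/- replicate 1 and without both end arrays, and the ER stress call without WT replicate 2, without C3aR-/- replicate 2 and without both. The cholesterol median was 0.12, 0.11 and 0.18 in these cases and 0.34 without WT replicate 3, and the ER stress median was -0.079, -0.059 and -0.015 and, without C3aR-/- replicate 1, -0.081. Without C3aR-/- replicate 1, Lss differed by 0.19, Hsd17b7 by 0.15 and Pdia3 by -0.20, and without WT replicate 1 Nsdhl by 0.17. In all, 23 of 36 lists passed camera with its preset correlation, 15 lower and 8 higher. With an estimated correlation 0 passed, 5 lists had an unadjusted p under 0.05, and fry called 1.

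No call was made for 13 lists. Podocyte genes had a median of 0.073, with Vegfa at 0.38 ± 0.15 and Nphs1, the slit diaphragm protein nephrin, at 0.26 ± 0.13 (0.17 without WT replicate 2). Mesangial and juxtaglomerular genes had a median of 0.095, with the angiotensin receptor Agtr1a at 0.30 ± 0.12, and renin-angiotensin genes one of 0.14, with the bradykinin receptor Bdkrb2 at -0.42 ± 0.15. The medians were 0.070 for the loop of Henle, -0.14 for medulla, 0.060 for endothelium, 0.15 for adipose tissue and -0.33 for neutrophils, with Egf at 0.60 ± 0.40 (0.12 without WT replicate 1 and 0.90 without WT replicate 2), Akr1b3 at -0.34 ± 0.17, Sox17 at 0.20 ± 0.12 (0.13 without WT replicate 3), Plin4 at 0.26 ± 0.12 (0.17 without C3aR-/- replicate 3) and Fpr2 at -0.58 ± 0.19. They were -0.020 for the oxidative stress response, with Cybb at -0.62 ± 0.20 and Cat at 0.43 ± 0.16, and 0.047 for glucose handling, with Pfkp at -0.30 ± 0.095. Lipid synthesis had a median of 0.097, the cell cycle one of -0.068 and genes higher in male kidney one of 0.16, with Scd2 at 0.30 ± 0.17 (0.19 without C3aR-/- replicate 1), Aurkb at -0.38 ± 0.20 (-0.18 without WT replicate 1) and Timd2 at -0.44 ± 0.15. Some of these lists were called in other settings. Podocyte genes were called without WT replicate 1 (median 0.10), without C3aR-/- replicate 2 (0.19), with array weights (0.24) and without both end arrays (0.21), and their median was 0.00062 without WT replicate 2. Mesangial genes were called without WT replicate 3 (0.22), without C3aR-/- replicate 2 (0.26), with array weights (0.25), without both end arrays (0.28) and with each probe on its own, and had a median of 0.00099 without WT replicate 2. The neutrophil median ran from -0.10 without WT replicate 1 to -0.52 without WT replicate 3, and was -0.034 with normexp correction, and the list was called without a filter and with each probe on its own. Lipid synthesis was called in 8 of 19 settings, among them without WT replicate 3 (0.19) and without C3aR-/- replicate 3 (0.21). The cell cycle was called in 10, lower without WT replicate 2 (-0.13), WT replicate 3 (-0.16) or C3aR-/- replicate 3 (-0.14) and higher without WT replicate 1 (0.10) and without both (0.11). Adipose (0.25) and endothelial genes (0.18) were called without WT replicate 3, medulla without WT replicate 2 (-0.16) and glucose handling without both (-0.080).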

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

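Leaving out both end arrays, the slide row as a block and the neighbours without immune genes were chosen after the data were seen. Immune genes here are members of the T cell, B cell, macrophage, neutrophil, chemokine, cytokine, Toll-like receptor, MHC and interferon lists. Genes picked by name, such as Clec, Klr and Cd genes, were added to them. No setting gave a gene past the adjusted threshold. The 2-fold count of 136 was 20 with normexp, 320 without a filter (66.6% lower, against 83.8%), 77 with the filter on all arrays, and 102 to 250 over the arrays left out in turn. The normexp offset shrinks folds of dim probes by construction, and fewer or more probes tested is part of the construction of the filters. The cause of the moves over the arrays left out was not tested. It was 158 with the slide row as a block, and 27 interferon, 16 chemokine, 11 MHC class I and 6 tubular injury members then passed over the list alone. The 23 lists became 15 without both end arrays, 0 with an estimated correlation and 1 with fry. The replicate block gave 150 genes in the 2-fold count, of which 130 were among the 136, and 24 lists. It took no gene past the adjusted threshold. With this block, 21 macrophage and 12 chemokine members passed over the list alone. Residuals of arrays with the same number correlated at 0.13, 0.41 and -0.09, and not every array correlated best with its own number. So few correlations, from groups this small, cannot decide whether the numbers pair the samples. The share of the fixed list of C3ar1 neighbours (16.4%) was 0% at the adjusted threshold, which no gene passed. It was 6.25% without immune genes (Fisher's exact p = 0.508). Among all genes within 5 Mb the share was 7.48% (Fisher's exact p = 0.173), and within 10 Mb 9.28% (Fisher's exact p = 0.00140).

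Directions turned as follows, and the cause was not tested. With array weights, medians were 0.048 for fibrosis, -0.028 for proximal tubule, 0.047 for medulla, -0.0029 for fatty acid oxidation, -0.037 for glucose handling, 0.00040 for the cell cycle, -0.072 for renin-angiotensin and -0.063 for male kidney genes. Medulla was 0.064 without a filter, adipose -0.030 with the filter on all arrays, and Lpl -0.019 as the mean of its probes. Without both end arrays, medians were 0.022 for inflammatory cytokines, 0.032 for fibrosis, -0.13 for proximal tubule, -0.043 for erythroid genes, -0.094 for fatty acid oxidation, -0.025 for lipid synthesis, -0.080 for glucose handling, -0.039 for oxidative phosphorylation, 0.011 for heat shock, 0.11 for the cell cycle, -0.13 for renin-angiotensin and -0.10 for male kidney genes, and Hba-a1 was -0.081 and Hbb-bt -0.12. Over the arrays left out in turn, medians ranged from -0.16 to 0.14 for medulla, -0.064 to 0.25 for adipose tissue, -0.015 to 0.14 for glucose handling, -0.16 to 0.10 for the cell cycle, -0.082 to 0.18 for renin-angiotensin, -0.053 to 0.27 for male kidney genes, -0.030 to 0.18 for endothelium, -0.058 to 0.027 for the oxidative stress response and -0.023 to 0.16 for the loop of Henle. All 36 lists kept their direction under quantile normalization, median scaling, normexp and the authors' table. Dim probes limit the sizes: Sh2d1a and Slamf6 were near the background, and normexp took the T cell median from -0.94 to -0.52.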

Other observations

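The tests on WT replicate 1, on naive B cell genes, on the interval around C3ar1 and on the splits of the samples were chosen after related values were seen; those on dim probes and on time of day were set before. Erythroid genes read higher in C3aR-/- cortex, 11 of 11 with a median of 0.56, including Hba-a1 (0.57 ± 0.39), Hbb-bt (0.63 ± 0.43), Alas2, which starts heme synthesis (0.68 ± 0.40), and Tfrc (0.33 ± 0.20). Without WT replicate 1 the first 3 were 0.15, 0.23 and 0.27, and without C3aR-/- replicate 2 the 4 were 0.34, 0.28, 0.41 and 0.13. The camera adjusted p was 0.00681 and the adjusted p with an estimated correlation was 0.455, and without WT replicate 1 (0.15) or C3aR-/- replicate 2 (0.29) the call ended, as it did with array weights (0.11), and without both the median was -0.043. Adrenal markers were higher in 10 of 11 (median 0.16), with Star (0.34 ± 0.16), Mc2r (0.49 ± 0.32), Hsd3b6 (0.34 ± 0.22) and Th (0.16 ± 0.095), at a camera adjusted p of 0.0319 and an adjusted p of 0.402 with an estimated correlation; the call ended without WT replicate 1, WT replicate 2, C3aR-/- replicate 1 (median 0.10) or C3aR-/- replicate 3, and also without a filter, with the filter on all arrays, with the mean of probes, with trend and robust variances and with the slide row as a block, which leaves it called in 10 of 19 settings. Mc2r differed by 0.13 without WT replicate 2 and 0.17 with normexp correction, Hsd3b6 by 0.13 without WT replicate 1 and 0.58 without WT replicate 2, and Star by 0.22 without WT replicate 1. Heat shock and immediate early genes were lower in 14 of 26 (median -0.071), led by Egr2 (-0.78 ± 0.25), Klf4 (-0.30 ± 0.10), Egr1 (-0.54 ± 0.28) and Btg2 (-0.31 ± 0.15), with a camera adjusted p of 0.0147 and an adjusted p of 0.546 with an estimated correlation, and the call ended without WT replicate 1 (median -0.051), without C3aR-/- replicate 2 (-0.013, with 3 members higher past adjustment over the list alone), with array weights (-0.023) and without both (0.011); Egr1 was -0.31 without WT replicate 1 and Btg2 -0.20 without C3aR-/- replicate 2.

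Lower T cell, chemokine and macrophage signals may reflect fewer leukocytes in C3aR-/- cortex, which the arrays cannot separate from lower expression per cell. For the T cell list the tables argue against WT replicate 1 alone, since without it the median was -0.90. WT replicate 1 was not the highest WT array on that list (0.49, against 0.59 for WT replicate 3). Without WT replicate 1 the chemokine median moved from -0.58 to -0.38 and the macrophage median from -0.54 to -0.39. The tables also argue against dimmer readings of weak probes in general. The lowest of 10000 random lists matched to the T cell list on mean signal had a median of -0.14. Lymphoid tissue in the WT samples stays open: 7 naive B cell genes had a median of -0.23, above the T cell median by 0.71 (95% bootstrap interval 0.11 to 1.16 over genes), but 4 of them were well above background on every array, too few to decide. The mean of the adipose list was -0.44, -0.51 and 0.72 on the WT arrays and 0.011, -0.27 and 0.48 on the C3aR-/- arrays. Within each group it ranked the arrays as the T cell list did, but its median difference was positive (0.15). Whether surrounding tissue differed between samples was not tested. With 10 splits of the arrays no share can fall under 0.1; the real split was the 1 split with a T cell median of that size (0.94, highest other 0.75), while 2 other splits (0.68 and 0.60) passed the interferon median of 0.56; the counts were 136 genes (highest other 147, reached or passed by 3 splits) and 23 lists (highest other 24, 2 splits), and 0 adjusted genes (highest other 1, all 10 splits). Of the 4 splits that put both arrays of slide row 2 on one side, 2 had 147 and 145 genes (2592 and 1948 at an unadjusted p under 0.05, against 1111) and 2 had 53 and 57 (930 and 480). The T cell median was -1.07 within row 1, -0.61 between the 2 arrays of row 2 and -0.94 with the row as a block.

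Clock genes were higher in C3aR-/- cortex in 15 of 20 members (median 0.25), with Per2 (0.65 ± 0.26), Usp2 (0.53 ± 0.17), Per3 (0.39 ± 0.16, with another probe opposite) and Tef (0.31 ± 0.14). The camera adjusted p was 0.00376, the adjusted p with an estimated correlation was 0.402, and without WT replicate 3 the call ended (adjusted p = 0.0852). The median was 0.15 with array weights (adjusted p = 0.0473). The Per2 and Dbp group was higher in 9 of 10 genes, with a median of 0.43. Tissue taken at another time of day that raised this group would lower genes that peak opposite to it. The 4 genes taken as opposite had a median of -0.046, with Arntl at -0.25 ± 0.14 and Nfil3 at -0.13 ± 0.11 but Cry1 at 0.30 ± 0.16 and Clock at 0.035 ± 0.12, named for this test. Not all of these need peak exactly opposite, so time of day and genotype cannot be told apart here.

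Genes of the fixed list of C3ar1 neighbours passed an unadjusted p of 0.05 more often than other genes, 11 of 67 or 16.4% against 4.85% (Fisher's exact test, two-sided, p = 0.000371). Of all 147 tested genes within 5 Mb, 7.48% passed, against 4.86% of other genes (Fisher's exact p = 0.173). The fixed list had a median of -0.12, with Klrd1 (-1.08 ± 0.20), Klrg1 (-1.25 ± 0.37), Klrk1 (-0.90 ± 0.27, another probe -0.26 ± 0.34) and Clec4n (-0.87 ± 0.27) leading. The camera adjusted p was 0.000281 and the adjusted p with an estimated correlation was 0.314. The median was -0.077 without WT replicate 3, -0.044 without C3aR-/- replicate 2, -0.060 with array weights, -0.058 with normexp correction and -0.027 without both end arrays, where the call ended (adjusted p = 0.0523), and with normexp correction Klrd1 differed by -0.55, Klrk1 by -0.55 and Klrg1 by -0.20. A candidate explanation is that the interval holds lectin receptor genes of leukocytes. Within 10 Mb, 38.5% of 39 immune genes passed, against 28.0% of immune genes elsewhere and 4.53% of other genes. This set also holds the interferon, MHC and NF-kB lists, so its shares are not rates for leukocyte markers alone. The remaining 252 genes within 10 Mb passed in 4.76% of cases, with an odds ratio of 1.05 (95% interval 0.54 to 1.89), which leaves flanking sequence of another strain open.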
